A study of Drosophila melanogaster with 3 samples.

How the data were processed

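The series holds 3 biological replicates of chromatin immunoprecipitation with an anti-GFP antibody from embryos of a fly line with GFP-tagged CG4424, with 1 technical replicate each, and chromatin was sonicated to fragments of 200 to 800 bp, per the labels. Replicates were named by the biological replicate number in the labels. The files are lists of regions, each with a signal value and a summit position. Per the notes deposited with each sample, the signal values come from the authors' region caller, run against a control alignment, and their scale is not stated. A relaxed list of peaks and background was made per replicate and another on the pooled reads, and the optimal set was thresholded by the authors on the irreproducible discovery rate, per the deposited notes. The caller, the aligner and their versions are not given in the sources used here. Signal values were compared within a list only, and between lists by rank. Lists were given on dm6 and dm3. All positions are on dm6, counted from 1, and dm3 served for an alternative count only. The list of replicate 2 ends at 30000 regions on both builds. All 6420 optimal regions were among the 6420 strongest of the pooled list, and they lie on 6396 distinct intervals, since a few intervals hold more than 1 summit. Each summit was counted. Read counts and control values were not used here, so no depth is given, and intervals cover counting error only.

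Annotation was Ensembl release 115 for the same assembly, without transposable elements, and the sequence was the matching RefSeq assembly. Starts were all annotated transcript starts on 2L, 2R, 3L, 3R, 4 and X. The lower-ranked regions were the 21288 pooled regions that overlap no optimal region. For spread between replicates, the 6420 strongest regions of each replicate were used, and the mean and SD of 3 values are given. The optimal set was drawn from these same replicates, so a direction shared with it is not an independent check. Overlap was at least 1 bp. A summit within 500 bp of a start was counted as promoter, and otherwise took 5' untranslated region, coding exon, 3' untranslated region, noncoding exon, intron or intergenic, in this order. A gene was occupied when an optimal summit lay within 500 bp of any of its starts, so genes with close starts can share a region. The 43 gene lists and 24 consensus sequences were written before the data were examined, and 9 listed names that did not match the annotation were not analysed here. Each list was compared with all other protein-coding genes (13945 in all, 24.9% occupied) or, for RNA genes, with other noncoding genes.

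Counts were compared with Fisher's exact test, paired windows with the exact McNemar test, arms with the exact binomial test and medians with a permutation test of 100000 resamples, all two-sided. Benjamini-Hochberg adjustment was made over the features, lists, consensus sequences, hexamers or arms, with a threshold of 0.05. For Fisher's exact test, an odds ratio with an empty cell had a small constant added to each cell. For paired windows, the odds ratio is that of summit-only to flank-only windows, with the constant always added to both counts. This pulls paired odds ratios from few windows towards 1, and keeps them finite where a count is empty. Intervals are exact (Clopper-Pearson) at 95%, and a count of 0 is given with the limit of 3 counts. Tests on regions or genes treat these as units, and neighbouring regions and genes are not fully independent. The genes named are those at the 20 strongest optimal regions, by the nearest protein-coding start within 1000 bp, the 4 members of highest signal of each list past the threshold, up to 2 of other lists, and CG4424. Genes near CG4424 and genes with many summits in their bodies were named after their values were seen. 1 gene that this rule names is not reported here. The 10 hexamers of highest odds ratio past the threshold are named. This rule, the tests and most alternatives were fixed before the data were examined. The alternatives cover a stricter set, each replicate left out, other windows, backgrounds and overlaps, and dm3. Leaving out a replicate means keeping the optimal regions overlapped by the strongest regions of both others, since the pooled calling could not be repeated here. For the mean replicate overlap alone, it means taking that replicate out of the mean.

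Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The steps were tested on simulated data. Overlaps matched those of an independent tool in 3000 of 3000 regions. For the gene list comparison, 92.0% of 100 simulated lists occupied at a raised rate were recovered and 0.279% of 716 other lists were called. For the hexamer comparison, both planted hexamers were recovered among 2080, and 4 of 2078 others were called, none of which lay apart from the planted site in sequence. List recovery was tried on the larger lists only, and simulated genes were occupied independently of each other. Recovery in small lists, shared regions and repeated gene copies were thus not covered. The simulated summits lay at random positions, without the low GC content of the real ones.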

Results

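Chromatin immunoprecipitation followed by sequencing was carried out on whole Drosophila melanogaster embryos of mixed sex, collected 0 to 16 h after laying, from a transgenic line that carries CG4424 with GFP fused to its C terminus. CG4424 encodes a zinc finger protein, and the anti-GFP antibody brought down the DNA it was attached to. The 3 biological replicates form 1 group, so the question the series answers is where in the genome the tagged protein was found. Each replicate has its own list of regions, with 22198 regions in replicate 1, 30000 in replicate 2 and 29796 in replicate 3 on genome build dm6. The list called on the pooled reads holds 29056 regions, and 6420 of them, called the optimal set here, were kept by the authors' reproducibility threshold. The numbers of reads are not used here, so read depth per replicate is unknown. Signal values ran from 186.2 to 12375 in the optimal set, with a median of 318.4.

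The region of highest signal lay at tna, a gene that interacts genetically with the Brahma chromatin remodelling complex, on chromosome 3L from 10856475 to 10858107, and its summit at 10857570 had a signal of 12375. A region with no protein-coding start within 1000 bp came next, in intergenic sequence of 3L from 10736790 to 10737597, with a signal of 10608. The summit at eIF4A, the RNA helicase of translation initiation, stood at position 5982456 of 2L, 93 bp from a start of the gene, and had a signal of 7358. An intron of Mob2, which encodes a kinase cofactor, carried a summit of signal 7172 at 11553625 of 3L, 513 bp from a start. The start of SRPK, a kinase of splicing factors, carried 6109 at 15380723 of 2R. This summit also lay within 500 bp of a start of dup, a member of the DNA replication list. The other named genes among the 20 strongest summits were CG14100 (signal 5314), Ugalt (5104), px (4666), Art3 (4293), Chro (4064), CG34299 (3931), Tcs5 (3813), mRpL41 (3730), ph-p (3436) and otk (3388). Of these 20 summits, 14 had a protein-coding start within 1000 bp and 13 lay in the promoter window of 500 bp. All 20 were overlapped by a region in each of the 3 replicate lists. The summit named for CG34299 lay 762 bp from its start, and within 500 bp of a start of the tRNA gene tRNA:Leu-TAG-1-2.

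The replicates placed the protein at largely the same regions. The 6420 strongest regions of replicate 1 overlapped 87.9% of the optimal regions, those of replicate 2 overlapped 91.7% and those of replicate 3 overlapped 89.7%, a mean of 89.8% ± 1.90 (SD, n = 3). Regions of the same widths placed at random on the same chromosomes overlapped 3.72% on average over 100 placements per replicate, and at most 4.31% in any placement. There were 4891 optimal regions (76.2%) overlapped by the strongest regions of all 3 replicates, and 19 regions were overlapped by those of none. Across regions, which are not independent replicates, the Spearman rho of signal values was 0.836 between replicates 1 and 2 over 6376 regions, 0.841 between 1 and 3 over 6390 regions, and 0.857 between 2 and 3 over 6389 regions. The optimal set was chosen by the authors from these same replicates, so the overlap is not an independent check.

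Promoters carried the largest share of the optimal summits. A summit lay within 500 bp of an annotated transcription start in 3004 of 6420 optimal regions (46.8%, exact binomial 95% interval 45.6 to 48.0), against 5216 of 21288 lower-ranked regions (24.5%), which are the pooled regions that overlap no optimal region. Fisher's exact test, two-sided, gave an odds ratio of 2.71 and p = 4.2e-244. The strongest 6420 regions of each replicate had a promoter share of 47.2% ± 1.93 (SD, n = 3), and the remaining regions of the same lists had 24.2% ± 0.917 (SD, n = 3). Random positions had 13.4%. Summits near starts were on the upstream side. In the promoter window the median optimal summit stood 110 bp upstream of the nearest start (-110 bp), 83.1% were upstream, and 57.3% were within 200 bp upstream. Lower-ranked summits in that window were upstream in 59.4% of cases, with a median position of -41 bp.

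**Figure D1:**
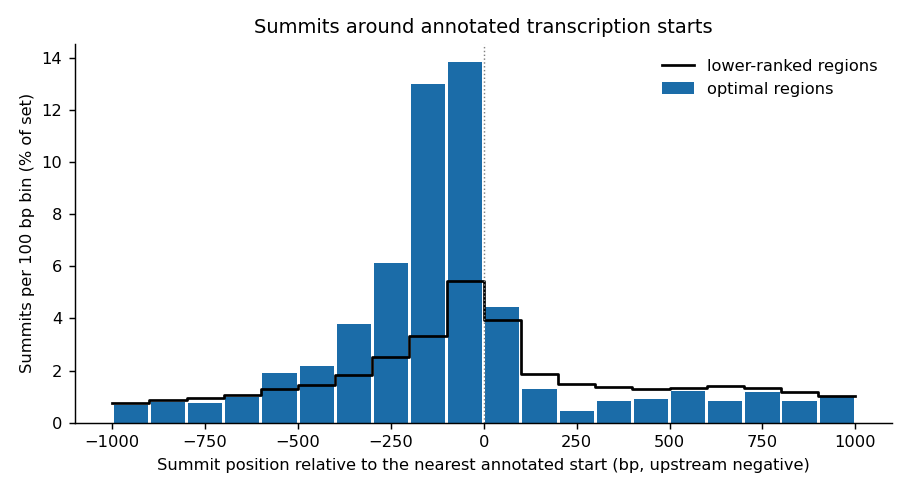
Share of all optimal summits (bars) and all lower-ranked summits (line) in 100 bp bins, by position relative to the nearest annotated start, in bp along the direction of transcription. The bin from -100 to 0 bp held 13.8% of the optimal and 5.42% of the lower-ranked summits.

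Exons and untranslated regions held few of the optimal summits. Coding exons held 0.296% of the optimal summits and 3.36% of the lower-ranked ones (odds ratio 0.0853, adjusted exact p = 8.8e-58), although 13.7% of random positions fell there. The 3' untranslated regions held 0.935% against 3.34% (odds ratio 0.273, adjusted exact p = 4.9e-30), and 5' untranslated regions outside the promoter window held 0.452% against 1.01% (odds ratio 0.447, adjusted exact p = 1.3e-05). Introns held 35.0% against 43.6% (odds ratio 0.698, adjusted exact p = 3.6e-34) and intergenic sequence held 15.4% against 23.3% (odds ratio 0.60, adjusted exact p = 2.7e-43). Noncoding exons did not differ past the threshold (1.06% against 0.902%, adjusted exact p = 0.268). These are Fisher's exact tests, two-sided, with Benjamini-Hochberg adjustment over 7 features, and each summit counts for a single feature. In the strongest regions of the replicates, introns held 35.0% ± 1.75 and intergenic sequence 15.2% ± 0.0768 (SD, n = 3).

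**Figure D2:**
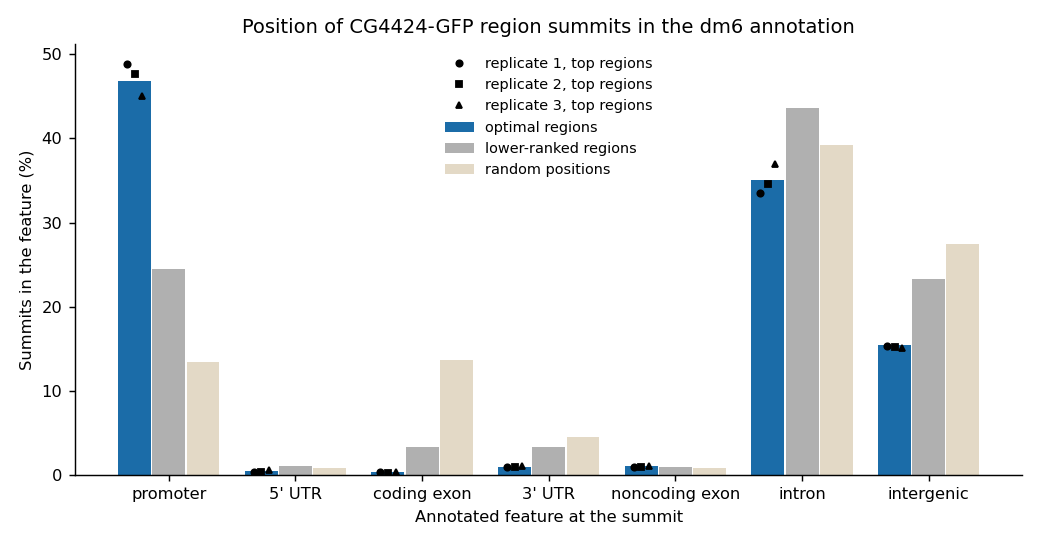
Percent of summits in each annotated feature for the optimal regions, the lower-ranked regions and random positions (bars), with the strongest 6420 regions of each replicate as points. Promoters rose from 24.5% in lower-ranked to 46.8% in optimal regions, and coding exons fell from 3.36% to 0.296%.

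Regions at promoters also had the higher signal. The median signal was 341.7 for the 3004 promoter regions and 302.1 for the other 3416 optimal regions, a difference of 39.6 (permutation test, two-sided, 100000 resamples, p = 1e-05, the smallest they can give). Promoter medians were higher in all 3 replicates, by a factor of 1.16 in replicate 1, 1.10 in replicate 2 and 1.14 in replicate 3. Of the 642 optimal regions with the highest signal 64.2% lay in the promoter window, and of the 642 with the lowest 41.3% did.

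Genes of the cytosolic ribosome stood out among the 43 gene lists. An optimal summit lay within 500 bp of a start in 68 of 86 cytosolic ribosomal protein genes (79.1%, exact 95% interval 69.0 to 87.1; 78.3% ± 1.78 over replicates, SD, n = 3), against 24.5% of other protein-coding genes (odds ratio 11.6, Fisher's exact test, adjusted exact p = 2.3e-24). The strongest were at RpS27 (FBgn0039300, 3R summit 25247521, signal 1597), RpL7 (FBgn0005593, 2L summit 10201037, signal 1357), RpL34b (FBgn0037686, signal 1128) and RpL32 (FBgn0002626, signal 1100). Mitochondrial ribosomal protein genes were occupied in 38 of 73 cases (52.1%; 52.5% ± 6.47, SD, n = 3; odds ratio 3.3, exact test, adjusted exact p = 6.8e-06), led by mRpS10 (signal 4293), mRpL41 (3730), mRpS23 (3236) and mRpL23 (2561). The mRpS10 region is the one at Art3 named above, since the starts of these genes lie close together. The mitochondrial list did not pass among genes with no other gene's start within 1000 bp, where 2 of 13 were occupied (odds ratio 1.18, adjusted exact p = 0.936), or when each region counted only for the gene of the nearest start (odds ratio 1.73, adjusted exact p = 0.139).

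Genes for splicing, transcription, chromosome architecture and the cell cycle were occupied more often as well. The spliceosome list had 22 of 37 members occupied (59.5%, odds ratio 4.45, exact test, adjusted exact p = 5.8e-05), with Sf3b6 (signal 774.8), U2af50 (767.5) and SF2 (635.8) in front. Architectural proteins, which organise chromosome contacts and boundaries, had 11 of 15 (73.3%, odds ratio 8.33, adjusted exact p = 5.2e-04), among them Chro (4064), Cp190 (1647), M1BP (838.1) and Trl (697.0), the gene of GAGA factor. The general transcription machinery had 32 of 68 (47.1%, odds ratio 2.70, adjusted exact p = 5.2e-04), with MED27 (1157), Polr2B (1032), Polr2H (904.9) and Nelf-E (884.2). Cell cycle genes had 17 of 30 (56.7%, odds ratio 3.96, adjusted exact p = 8.5e-04), with CycE (989.9), Dp (849.2), aurA (607.4) and tefu (606.6). The Notch pathway and E(spl) complex had 9 of 15 (odds ratio 4.54, adjusted exact p = 0.0144), with E(spl)m3-HLH (1459), numb (1107), E(spl)m7-HLH (732.4) and E(spl)mdelta-HLH (620.3). Autophagy and lysosome genes had 12 of 24 (odds ratio 3.03, adjusted exact p = 0.0261), with Atg17 (980.4), Atg2 (887.0), Atg9 (715.3) and Atg4b (628.8). Among noncoding genes, 7 of 32 snRNA genes were occupied against 7.71% of the others (odds ratio 3.35, adjusted exact p = 0.0314), with the pair snRNA:U6:96Ab and snRNA:U6:96Ac at 1 shared region (340.6), snRNA:U2:34ABb (260.4) and snRNA:U1:95Ca (248.0). Counting each region only for the gene of the nearest start ended the calls of the spliceosome (odds ratio 1.94, adjusted exact p = 0.196), architectural (3.06, 0.125), transcription (1.53, 0.302), Notch (4.02, 0.0531) and autophagy (2.75, 0.0976) lists. Among genes with no other gene's start within 1000 bp, the transcription (1.39, adjusted exact p = 0.835), cell cycle (4.64, 0.114), Notch (3.24, 0.509), autophagy (1.08) and snRNA (2.84, 0.509) lists did not pass. Among the 3210 regions of higher signal the spliceosome (odds ratio 1.84, adjusted exact p = 0.308), Notch (0.188), autophagy (0.349) and snRNA (0.570) lists did not pass. The Notch list also did not pass within 250 bp (adjusted exact p = 0.316), nor the Notch (0.0530), autophagy (0.0917) and snRNA (0.100) lists within 1000 bp. With the optimal regions limited to those shared by the strongest regions of the other replicates, the spliceosome list had odds ratios of 2.57 without replicate 1 and 2.60 without replicate 2, and the Notch list had adjusted exact p = 0.213 without replicate 1 and 0.200 without replicate 2, autophagy genes had 0.176, 0.173 and 0.0698 without replicates 1, 2 and 3, and snRNA genes had 0.124 without replicate 2 and 0.145 without replicate 3.

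Genes for sensory receptors, cuticle, male reproductive proteins, proteases and canonical histones were occupied less often than other genes. Odorant, gustatory and ionotropic receptor genes had a summit at 2 of 179 members (1.12%, odds ratio 0.0336, exact test, adjusted exact p = 2.4e-18), at Ir67c (signal 197.7) and Ir60e (189.9), and odds ratios of 0.0208, 0.0104 and 0.0200 without replicates 1, 2 and 3. The list of epidermis and cuticle proteins had 3 of 132 (2.27%, odds ratio 0.0694, adjusted exact p = 8.0e-12). Of those 3, Cpr72Eb (201.5) encodes a cuticle protein, while grh (342.1) encodes a transcription factor of the epidermis and Cpr (292.3) encodes cytochrome P450 reductase and came into the list through its name. Male accessory gland and sperm protein genes had 2 of 62 (3.23%, odds ratio 0.100, adjusted exact p = 5.9e-05), at Sfp26Ad (613.6) and Mst85C (319.0). The Mst85C region also lay within 500 bp of a start of Rel, a member of the antimicrobial peptide and immune receptor list. Serine protease and digestion genes had 0 of 25 (adjusted exact p = 0.0064), which allows a share of up to 12%. Canonical histone genes had 0 of 111 (adjusted exact p = 3.3e-13), which allows up to 2.70% (3.27% by the exact interval) if each counts as an independent gene. They are near-identical repeated copies and not independent, so this p-value and these limits are too small. How reads from repeats were placed is not given in the sources used here. Among genes with no other gene's start within 1000 bp the male reproductive and histone lists (both adjusted exact p = 0.342) and the protease list (0.509) did not pass, and the protease list also did not among the 3210 regions of higher signal (0.150) or by the nearest start (0.0651). All 14 lists past the threshold, 9 higher and 5 lower, had the same direction in 3 of 3 replicates. Most lists not past it did as well. The replicates' strongest regions largely overlap the optimal set, so this does not set the 14 lists apart.

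**Figure D3:**
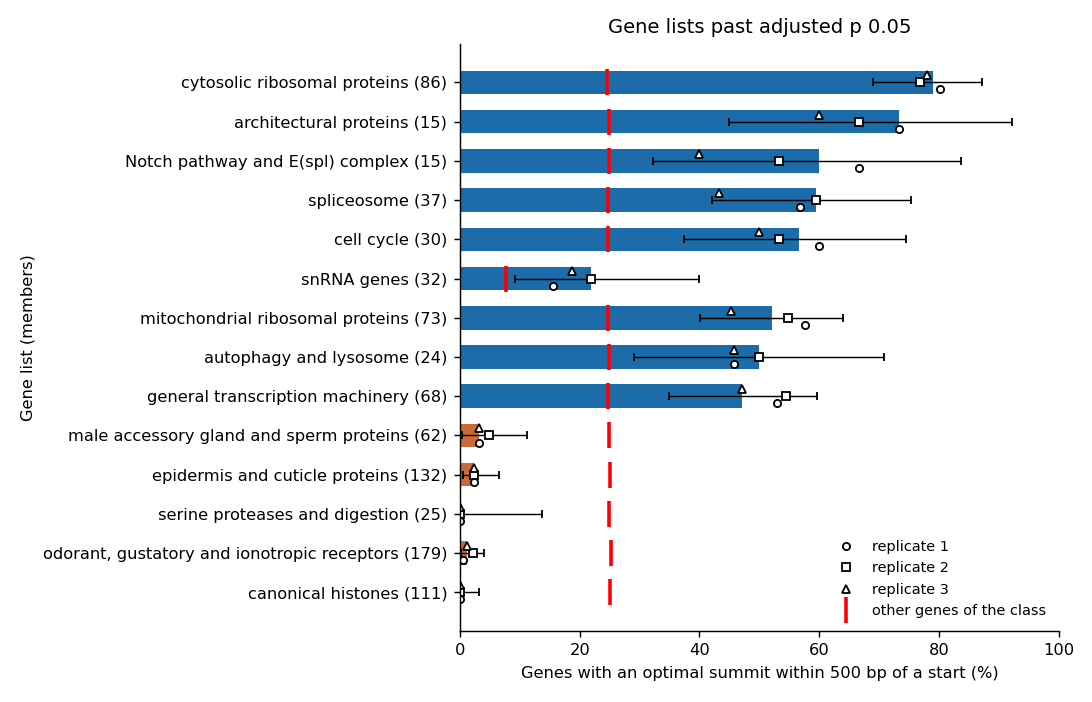
Percent of the members of each of the 14 gene lists past adjusted p 0.05 that had an optimal summit within 500 bp of a start (bars, with exact 95% intervals), with each replicate's strongest 6420 regions as points and the other genes of the same class as red marks. Cytosolic ribosomal protein genes reached 79.1% and receptor genes 1.12%.

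The remaining 29 lists did not pass the threshold. Zinc finger genes of the ZAD family and relatives, to which CG4424 belongs, had 27 of 72 occupied (37.5% against 24.8%, odds ratio 1.82, exact test, adjusted exact p = 0.0551), with trem and idc at 1 shared region (signal 1182). That list passed in 4 of 8 other ways of counting fixed beforehand, with adjusted exact p = 0.0445 among the 3210 regions of higher signal, 0.0446 without replicate 1, 0.0315 without replicate 3 and 0.0410 within 250 bp. It did not pass without replicate 2 (adjusted exact p = 0.0858), within 1000 bp (0.135), by the nearest start (0.359) or among genes with no close neighbour, where 3 of 29 were occupied and the odds ratio was 0.745. Trithorax group and remodeller genes had 11 of 24 (adjusted exact p = 0.0800), with brm at 1480, and passed in 1 of 8 such ways of counting, within 1000 bp (0.0352). Translation initiation and elongation genes had 20 of 53 (adjusted exact p = 0.0891), led by eIF4A (7358) and eIF6 (2194). They passed in 2 of 8 such ways of counting, among the regions of higher signal (0.0445) and within 250 bp (0.0283). Respiratory chain genes had 25 of 91 (27.5%, adjusted exact p = 0.669). The 1 occupied member of the chorion and vitelline list was Cp190, which is not a chorion gene and entered by its name. Within 250 bp the neuroblast and neuron list (odds ratio 0.0784, adjusted exact p = 0.0207) and the antimicrobial list (0.0851, 0.0283) passed, and within 1000 bp snoRNA genes did (2.18, 5.7e-06), each in 1 of 8 ways of counting. Gap and maternal genes, led by bcd (565.6), had 2 of 15 (13.3% against 24.9%, adjusted exact p = 0.501), and Hox genes had 1 of 8, Dfd (365.1), against 24.9% (adjusted exact p = 0.822). The dorsoventral list had 1 of 21, dl (205.0), with odds ratio 0.151 and adjusted exact p = 0.0891. It passed without replicate 1 (adjusted exact p = 0.0446), without replicate 2 (0.0462) and within 250 bp (0.0356), and did not pass without replicate 3 (0.162), among the regions of higher signal (0.188), within 1000 bp (0.358), by the nearest start (0.302) or among genes with no close neighbour (0.509).

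Known sequence elements differed between the windows within 50 bp of the summits and windows of the same width centred 500 bp away at the lower coordinate. The CTCF core occurred at 1.45% of optimal summits and 0.218% of their flanks (odds ratio 6.45, exact McNemar test, two-sided, adjusted exact p = 7.0e-15), and at 1.35% ± 0.283 in the replicates (SD, n = 3). The palindrome TATCGATA, recognised by DREF and BEAF-32, occurred at 1.96% against 0.280% (odds ratio 6.84, adjusted exact p = 2.3e-20; 1.82% ± 0.292 in the replicates, SD, n = 3). The core promoter elements Motif 1 (0.452% against 0.0467%), Ohler motif 6 (0.405% against 0.0467%) and Ohler motif 7 (2.32% against 0.919%) were also higher, as were the BEAF-32 core, the TATA box, the initiator, the Su(Hw) core, the homeodomain site (10.4% against 5.78%) and the GATA site (21.7% against 15.2%). The GAGA element was lower (0.966% against 2.91%, odds ratio 0.315, adjusted exact p = 9.9e-16), with the CLAMP GA repeat, the Zw5 site, the E-box and the E2F site. In all, 11 of 24 consensus sequences were higher and 5 were lower, and these 16 had the same direction in 3 of 3 replicates. The replicates' strongest regions largely overlap the optimal set, so the shared direction is not an independent check. The heat shock element did not pass (odds ratio 1.25, adjusted exact p = 0.0503), and passed in 5 of 9 other ways of counting fixed beforehand, with odds ratios of 1.10 to 1.47 over all 9. Odds ratios from few windows moved with the replicates, to 5.29 and 5.57 for Motif 1 and to 35 and 12.3 for the Su(Hw) core without replicates 1 and 2, against 8.43 and 3.55 with all. Within 25 bp of the summits the initiator (odds ratio 1.11, adjusted exact p = 0.0928) and the Su(Hw) core (3.4, 0.154) did not pass. Against lower-ranked summits of equal GC content, a background chosen after the data were seen, 5 of these 16 kept their call and direction, the CTCF core (odds ratio 5.23), Ohler motif 7 (3.03), TATCGATA (2.74), Motif 1 (3.42) and the BEAF-32 core (1.56). The TATA box was lower there (0.777), and the Ets site (1.63, higher) and the TCT element (0.920, lower), which had not passed against flanks, passed there. All 5 elements lower than in flanks lost their call there, with odds ratios of 0.953 for GAGA, 0.648 for the CLAMP repeat, 1.13 for Zw5, 0.861 for the E-box and 0.969 for E2F, as did Ohler motif 6 (1.30), the initiator (0.958), the Su(Hw) core (1.06), the homeodomain (0.997) and the GATA (1.04) sites. Against all lower-ranked summits, not matched, Motif 1 (odds ratio 1.34, adjusted exact p = 0.291), Ohler motif 6 (0.0568), the TATA box (0.278), the initiator (0.360), the E-box (0.0800) and the Su(Hw) core (0.850) did not pass, while the DPE (odds ratio 1.10, adjusted exact p = 0.0019) and Pho (0.832, 0.0163) sites, which had not passed against flanks, did. Pho also passed within 100 bp of the summits (adjusted exact p = 0.0019) and against the flank on the other side (0.0011), the DPE more than 500 bp from any start (0.0113), Zelda (0.0103) and TCT (0.0019) within 100 bp, and CREB/ATF more than 500 bp from any start (0.0288). More than 500 bp from any start, TATCGATA had an odds ratio of 1.21 (adjusted exact p = 0.860), the BEAF-32 core 1.07 (0.45) and Ohler motif 7 0.869 (0.752), and Motif 1 (0.45), Ohler motif 6 (0.385) and the initiator (0.0939) did not pass either.

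Hexamers followed base composition. The mean GC content was 33.2% at optimal summits, 44.1% in their flanks, 38.8% at lower-ranked summits and 42.2% at random positions, and the replicates' strongest regions had 33.6% ± 1.06 (SD, n = 3). Of all hexamers, counted on either strand, 529 were higher and 1086 lower at summits (exact McNemar tests, adjusted p under 0.05). All 36 hexamers without G or C were higher, and 225 of 228 with at least 5 G or C bases were lower. The 10 of highest odds ratio were ATATTA (21.4% of summits against 6.87% of flanks, odds ratio 3.63), CTAGTA (3.47), ATACTA (3.44), TTTAAA (3.21), AAATAT (3.18), TACTAA (3.15), TATTAA (3.12), AATATA (3.09), ATTTAA (3.02) and AATATT (2.99). Against lower-ranked summits in place of flanks 1346 hexamers passed when as many were drawn at random, and 219, 140 higher and 79 lower, when they were matched on GC content. Of the 219, 141 had passed against flanks in the same direction and 37 in the other. Among the named hexamers, AATATA and AATATT were not higher against the matched summits.

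**Figure D4:**
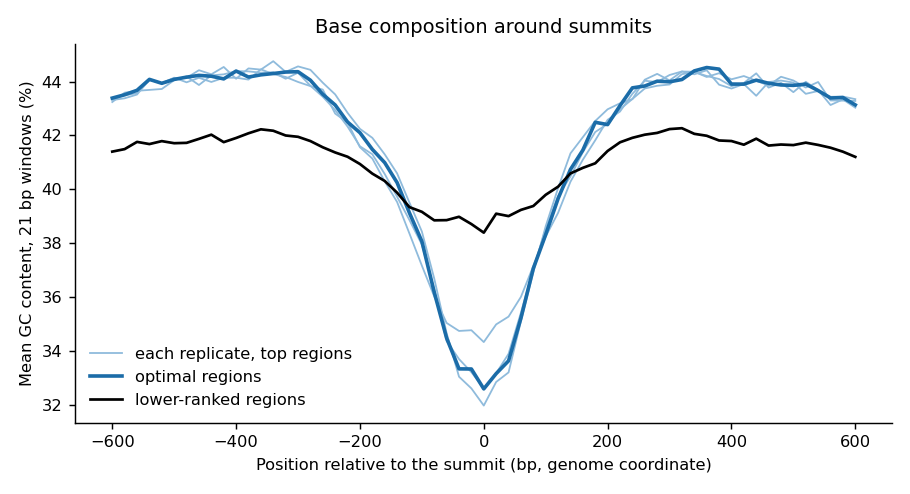
Mean GC content in 21 bp windows by position relative to the summit, in bp, for the optimal regions, the strongest 6420 regions of each replicate and the lower-ranked regions. At the summit the optimal regions stood at 32.6% and the lower-ranked ones at 38.4%.

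Chromosome 4, the small and mostly heterochromatic chromosome, carried fewer regions than its length gives. It had 30 optimal regions, 22.3 per Mb, a ratio of 0.464 to the share of its length (exact binomial test, two-sided, adjusted exact p = 1.4e-05) and of 0.606 to its share of annotated starts (adjusted exact p = 0.0083). The ratio to length was 0.50 ± 0.0763 in the replicates (SD, n = 3). Arm 2R was lower by both measures, at 0.918 of its length share (adjusted exact p = 0.0043) and 0.836 of its start share (adjusted exact p = 5.3e-11). Arm 3L was higher at 1.05 (adjusted exact p = 0.0427) and 1.15 (adjusted exact p = 2.2e-08), but against length it was no longer past the threshold without replicate 1 (0.150), 2 (0.283) or 3 (0.375). Arm 2L was higher by length (1.08, adjusted exact p = 0.0111) and not by starts (0.971, adjusted exact p = 0.300). The X chromosome stood at 1.01 of its length share (adjusted exact p = 0.718) and 1.08 of its start share (adjusted exact p = 0.0091). Arm 3R did not pass the threshold by either measure. Of the arms past the threshold by length, only chromosome 4 still passed among the 3210 regions of higher signal.

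CG4424 itself (FBgn0038765, 3R from 20026487 to 20028040, minus strand) had no optimal summit within 500 bp of a start. The summit nearest to its start, at 20028108, belonged to a lower-ranked region of signal 96.05. The gene next to it on the other strand, CG4854, named after its values were seen, had this lower-ranked summit 50 bp from its start and no optimal one within 500 bp. The 5 optimal summits within 20 kb stood at PIG-L (20021355, signal 1243), psidin (20021557, signal 965.2), idc (20031611, signal 1182), Regnase-1 (20036181, signal 777.4) and MED25 (20008837, signal 355.6).

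**Figure D5:**
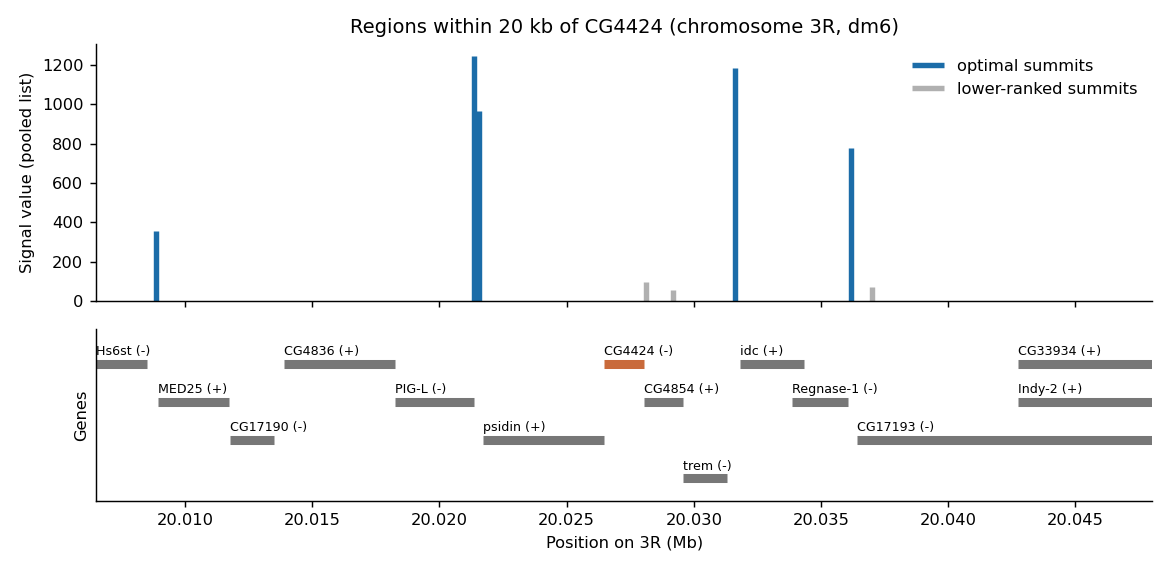
Signal value of each summit within 20 kb of CG4424 in the pooled list (vertical lines, blue for optimal and grey for lower-ranked), above the annotated genes with their strands, by position on 3R in Mb of dm6. The 5 optimal summits stood at the starts of other genes and none at CG4424.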

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

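The tests against backgrounds of equal GC content, against randomly drawn lower-ranked summits and among genes with close neighbours were chosen only after the results were seen. The direction and call of the promoter share and of the promoter signal difference held under every alternative run, with odds ratios of 2.39 to 5.67 and median differences of 27.4 to 61.6. The mean replicate overlap was 81.1% when at least 50% of both regions had to overlap, 85.5% for summits within 100 bp and 99.7% for the whole list of each replicate, since a longer list overlaps more. With a replicate left out of the mean and the optimal set unchanged, the mean overlap was 88.8% to 90.7%. This range follows from the replicate values already given and is no further test. The 14 gene lists past the threshold became 7 when each region counted only for the gene of the nearest start. They became 3 without genes whose start lies within 1000 bp of another gene's start, where 9252 genes are left out and lists shrink, and where the spliceosome and architectural lists had under 4 members left and were not tested. Among those genes alone, 11 lists passed. Cytosolic ribosomal proteins, receptors and cuticle proteins passed under every alternative planned. snoRNA genes turned to an odds ratio of 2.18 with a promoter window of 1000 bp and passed the threshold there, and the cause was not tested. Against lower-ranked summits of equal GC content 8 consensus sequences passed in place of 16, with 5 in both and of 1 direction, and 219 hexamers in place of 1615. That change is of the background and the composition together: as many lower-ranked summits drawn at random gave 12 and 1346. Of the 12840 matched windows 8904 were distinct, so their p-values are somewhat too small. Among consensus sequences and named hexamers past the threshold in either comparison, the odds ratio crossed 1 for the TATA box (0.777), the initiator (0.958), the TCT element (0.920), the homeodomain site (0.997), the Zw5 site (1.13), the Ets site (1.63), AATATA (0.949) and AATATT (0.982). Of these consensus sequences, the TATA box, the TCT element and the Ets site passed against matched summits, and the initiator, homeodomain and Zw5 sites did not. The odds ratio also crossed 1, without passing, for the Su(Hw) core (0.90) against all lower-ranked summits and for Ohler motif 7 (0.869) more than 500 bp from any start. Of 4 chromosome arms past the threshold, 1 (chromosome 4) passed in the stricter set of 3210 regions, and 2L turned to 0.971 against annotated starts. Arms by length were not run on dm3, whose lengths were not used here. Read depth, which limits how many weak regions can be called, was not used here.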

Other observations

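The tests in this part were chosen after the results were seen, except that of gene starts near CG4424. Genes that share a promoter region with a neighbour were occupied more often than others. Of 5052 protein-coding genes with a partner gene starting on the opposite strand within 1000 bp upstream, 2193 had an optimal summit at a start (43.4%, exact 95% interval 42.0 to 44.8), against 1276 of 8893 other protein-coding genes (14.3%, interval 13.6 to 15.1), an odds ratio of 4.58. The share was higher in each replicate, at 45.5%, 44.6% and 41.4% against 14.6%, 14.8% and 13.4%. These shares count 1 region for both genes of a pair. With each region counted only for the gene of the nearest start, 1293 genes with a partner (25.6%) and 1206 others (13.6%) were occupied, an odds ratio of 2.19. Several long genes, picked for having the most summits within their bodies, differed in density. kirre, which encodes a cell adhesion protein of muscle founder cells, held 26 over 394.1 kb, or 0.66 per 10 kb, against 0.484 per 10 kb on the whole X chromosome. Denser were CG1677 (20 summits, 1.6 per 10 kb), shn (15, or 2.57), tna (15, or 3.66), ush (14, or 2.18), rdx (13, or 2.00), sbb (13, or 1.64), pnt (12, or 2.15) and CHES-1-like (12, or 4.44), while hth held 12, or 0.909 per 10 kb, and Ten-a 12, or 0.412, below its arm. The arms of these genes held 0.440 to 0.516 per 10 kb.

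Against lower-ranked summits of equal GC content, 96 of 32896 octamers were higher at optimal summits and 35 were lower (Fisher's exact tests, Benjamini-Hochberg adjustment). A matched window drawn more than once counted each time, which makes these p-values somewhat too small. The matching was on GC content only, and 46.8% of all optimal but 24.5% of all lower-ranked summits lay in the promoter window. Sequences common at promoters can therefore differ through that share. Against flanks, more than 500 bp from any start, TATCGATA had an odds ratio of 1.21 and did not pass. CAACACTG stood at 1.68% of summits against 0.436% (odds ratio 3.91, adjusted exact p = 5.7e-13; 1.71% ± 0.357 in the replicates, SD, n = 3). CAGCCCTG stood at 0.826% against 0.0935% (odds ratio 8.90, adjusted exact p = 1.3e-11), TATCGATA at 1.96% against 0.724% (odds ratio 2.74), AACTATCG at 1.39% against 0.413% (odds ratio 3.39), AGGTGGCG at 0.810% against 0.125% (odds ratio 6.545) and AGATGGCG at 1.12% against 0.280% (odds ratio 4.03). The last 2 resemble the CTCF core. CAGCCCTG matches the inner bases of Ohler motif 7, and TATCGATA and AACTATCG contain the BEAF-32 core on either strand. CAAAAAAA (3.52% against 6.35%) and AAAAAAAA (7.87% against 11.6%) were lower.

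Optimal summits were poor in G and C, and the more so the stronger the region, from 35.5% in the 642 regions of lowest signal to 30.8% in the 642 of highest signal. Promoter location does not account for it: more than 500 bp from any start, optimal minus lower-ranked summits gave -6.09 points (SE 0.158). A preference of the libraries or of mapping for AT-rich fragments stays open, since lower-ranked summits from the same libraries also lay below random positions (-3.29 points, SE 0.0983), which weak binding could give as well. No biological explanation was tested, as the design has 1 group.

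For the 68 occupied cytosolic ribosomal protein genes, crowded starts are not the whole source, since the odds ratio was 8.16 among genes with no other gene's start within 1000 bp, where 10 of 18 were occupied. Relative to respiratory chain, proteasome and V-ATPase genes, of which 51 of 156 were occupied (32.7%), the odds ratio was 7.78 (Fisher's exact test, p = 2.8e-12). These lists were picked after their shares were seen, and some of their genes have tissue-specific forms. Spliceosome (59.5%), mitochondrial ribosomal protein (52.1%) and general transcription machinery (47.1%) genes, left out there, were occupied more often, and DNA replication genes (32.4%) were not. Each share stayed below the 79.1% of cytosolic ribosomal protein genes. So the comparison does not decide whether all constitutively used genes carry a signal at their starts. A signal that follows the strength of transcription stays open, since occupied ribosomal protein gene starts had a median signal 1.32 times that of other occupied genes (492.9 against 372.2, permutation p = 0.0050), and no expression values were used here. No biological explanation was tested.

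Within 20 kb of CG4424 lay 3 of the 642 optimal regions of highest signal, a number that 1.25% of 3747 genes of like length reached or passed. Many gene starts nearby do not account for it alone, since 2.49% of the 762 genes with at least as many starts (13) had 3 or more such regions. The summits at PIG-L (20021355) and psidin (20021557), which are among the 3, lie close together. Windows of neighbouring genes overlap, so these shares do not come from independent windows. Extra copies of the locus in the transgenic line stay open, since the 8 pooled regions there, optimal and lower-ranked, lay within the spread of genes of like length (37.1% had as many or fewer and 69.0% as many or more, with a median of 10). Of optimal regions of any signal there were 5, against a median of 3, and 77.2% of genes had fewer, so the binding there is not shown to be dense.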
